A study of Mus musculus with 6 samples.

How the data were processed

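Gene expression was measured by mRNA sequencing of mouse lung tumours, 3 control and 3 Keap1 knockout samples. The deposited count table holds whole-number read counts per Ensembl gene for the 6 samples, without normalization, and its columns were matched to samples by the names the labels give. Reads were aligned with STAR to the mm39 build, per the submitters' processing notes. The counting tool, its annotation release, its treatment of strand and of reads that fit several genes are not given in the sources used here, so counts of near-identical gene copies and of overlapping or antisense genes are uncertain. The authors' deposited table of their comparison gives log2 fold changes, a Wald score, p-values and adjusted p-values per gene symbol, and was made with DESeq2 per the submitters' processing notes and the file headers. Positive values there mean higher in the knockout, which was checked against the counts. Gene symbols were taken from a table of gene names that paired 52073 of the 56980 identifiers with a symbol, including 17548 of the 17901 tested. The genome annotation at hand belongs to an earlier mouse build than mm39, so no coordinates are given.

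Total counts ranged from 18731515 to 23759892 per library, and mitochondrially encoded genes took 0.981% to 1.41% of them. Genes were filtered with filterByExpr, library totals were taken again over the genes kept, scaled by TMM, and genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, two-sided) in a model with genotype as its only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are CPM, counts scaled to the same TMM-adjusted total in every library, with the SD over 3 samples, and principal components and correlations used log2 CPM with a prior count of 2. Where a group had no reads, the fold is a lower bound against 3 counts over the group, and with 1 to 3 reads it is the ratio of reads pooled over each group to their pooled scaled totals, with a 95% Poisson interval. Such bounds and intervals cover counting error only. Fitted fold changes of these genes depend on the prior count.

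A total of 41 gene lists, covering NRF2 targets, lineage, signalling, metabolism, immune functions and markers of other cell types, were fixed before the data were examined, together with the tests and alternatives. Each list was tested with camera on voom values (limma 3.58.1, preset correlation 0.01, adjustment over the 41 lists), again with an estimated correlation, and with fry. Named genes followed a rule fixed at the same time: Keap1, a set of genes named in advance, the 10 largest changes in each direction among genes past the threshold with a mean of at least 5 CPM and with the groups apart, and in each list up to 4 members past the threshold or, where none passed, the 2 with the smallest p. Genes outside the rule were chosen after their values were seen, among them Krt5, Krt14, Trp63, Col1a1, Mmp13, Chga, Calca, Krt8, Krt18, Nkx2-1, Aldh3a1, Mycl, Mycn, Mki67, Top2a, C1qc, C1qb, Fcgr1, Slc40a1, Fech, Abcg2, Slc30a3 and Calr3.

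The edgeR step was tested on simulated counts drawn from the means, depths and within-group spread of these 17901 genes. In these counts 200 genes were changed and 20 others raised as a list. The step recovered 0 of 67 genes at an absolute log2 fold change of 1, 5 of 67 at 2 and 33 of 66 at 4. It made 2 calls among 17681 unchanged genes. Few genes changed in the simulation, whereas in the data 5493 had an unadjusted p below 0.05 by edgeR. The Benjamini-Hochberg adjustment was therefore stricter in the simulation, and these shares do not give the recovery in the data. Camera called a simulated raised list and did not call an unchanged one. The draws took means, depths and spread from the data, not correlations between genes. In the data the estimated correlations within lists ran from -0.139 (subtype factors and MYC family) to 0.901 (MHC class II), against the preset 0.01. This check therefore cannot tell how often camera calls unchanged lists whose members vary together. The alternatives were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma voom, each sample left out in turn, the sample number as a block, a log2 fold threshold of 1 and an adjusted p below 0.1, and for lists an estimated correlation and fry. A limma voom fit with a spread per genotype and an edgeR fit with Xist level as a term were added after the data were seen. No sample was left out of the comparison. Results for some genes are not reported here.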

Results

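The series profiled mouse lung tumours of small cell lung cancer, an aggressive neuroendocrine carcinoma, about 4 months after virus was given to start the tumours. It followed a screen of 18 putative tumour suppressors that measured tumour growth with DNA barcodes, and it asked how loss of Keap1 alters gene expression in tumours of a mouse model labelled QKO. KEAP1 is the adaptor that marks the transcription factor NRF2 for degradation, and NRF2 switches on genes for glutathione synthesis and detoxification. Messenger RNA was sequenced from 3 control and 3 Keap1 knockout samples. The labels do not spell out QKO, state how Keap1 was inactivated or say whether the samples of a group came from separate animals, so p-values measure the spread between these samples. Reads counted on genes totalled 20065069, 19881823 and 18731515 in controls 1 to 3 and 21801647, 22786776 and 23759892 in knockouts 1 to 3. Of 56980 Ensembl gene identifiers, 17901 passed the filter on low counts and were tested.

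Keap1 RNA itself was present at similar levels in both groups. Keap1 (ENSMUSG00000003308) stood at 78.4, 74.5 and 58.7 CPM (counts scaled to library totals) in controls 1 to 3 and at 67.5, 93.0 and 79.9 CPM in knockouts 1 to 3, with means of 70.5 ± 10.4 and 80.2 ± 12.8 CPM (SD, n = 3 each). The log2 fold change was 0.18 ± 0.20 (SE), with an adjusted p of 0.564 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Gene disruption need not lower the amount of transcript, so this level neither checks nor contradicts the genotype labels.

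The 3 knockout libraries resembled each other closely, whereas each control library carried a gene program of its own. Pearson correlations of log2 CPM between knockout libraries were 0.968, 0.964 and 0.979 across genes. Controls 1 and 2 correlated at 0.912, and control 3 at 0.815 and 0.821 with them. The first principal component held 56.5% of the variance and placed control 3 at -178, controls 1 and 2 at -41.1 and -41.7, and the knockouts between 77.5 and 95.6. The median gene had a standard deviation of 0.578 in log2 CPM among controls and 0.222 among knockouts, a ratio of 2.61. An exact permutation test of this ratio over the 20 assignments gave a two-sided p of 0.1, the smallest that 3 against 3 allows. Assignments that mix the genotypes add the difference between group means to both standard deviations. This p therefore does not measure the difference in spread alone. No pair of libraries agreed within sampling noise.

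**Figure D1:**
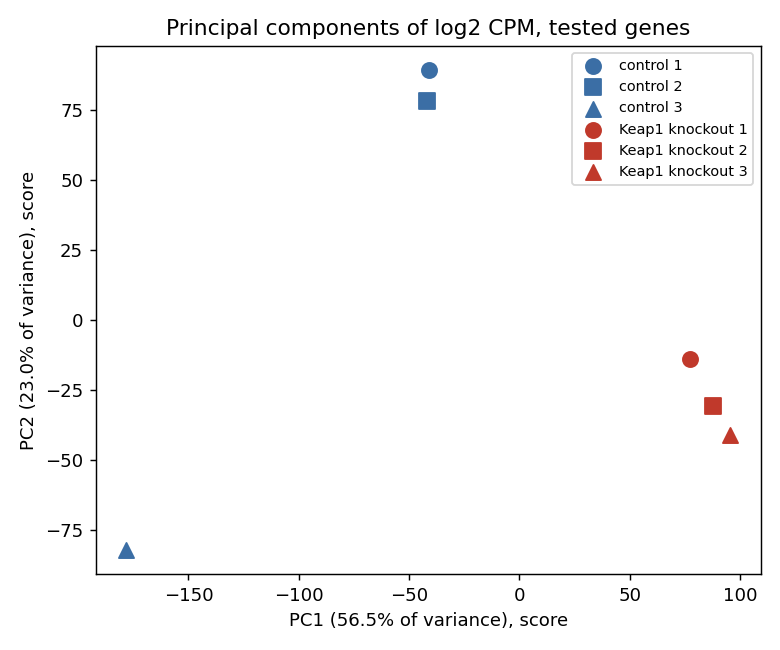
Scores of the 6 libraries on the first and second principal component of log2 CPM over the tested genes, 1 point per library (blue control, red Keap1 knockout, marker shape by sample number). The knockouts lie together at PC1 scores of 77.5 to 95.6, and control 3 lies apart at -178.

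Lineage genes differed between the control libraries. Control 1 held squamous and basal epithelial transcripts: the basal keratins Krt5 and Krt14 reached 2040 and 3370 CPM and the basal transcription factor Trp63 231 CPM, against at most 54.8 CPM of any of these genes in every other library. Control 2 held matrix transcripts, with 20400 CPM of the collagen gene Col1a1 and 1760 CPM of the collagenase gene Mmp13. Control 3 held neuroendocrine transcripts, with 948 CPM of the granule protein gene Chga and 622 CPM of the transcription factor gene Insm1. The neuronal factor Neurod1, which the filter left untested, had 1923 reads in control 3 and at most 4 in any other library. Pou2f3, the tuft cell factor, had 17 reads at most and was not tested. Under a rule set after the data were seen, at least 20 CPM and 20 times the level of every other library, control 1 had 51 such genes, control 2 had 28 and control 3 had 270, and no knockout library had any. The lung lineage factor Nkx2-1 was present throughout, at 410 ± 110 CPM in controls and 395 ± 31.6 CPM in knockouts (SD, n = 3 each). The genes of this paragraph other than Insm1, Neurod1 and Pou2f3 were chosen after their values were seen.

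**Figure D2:**
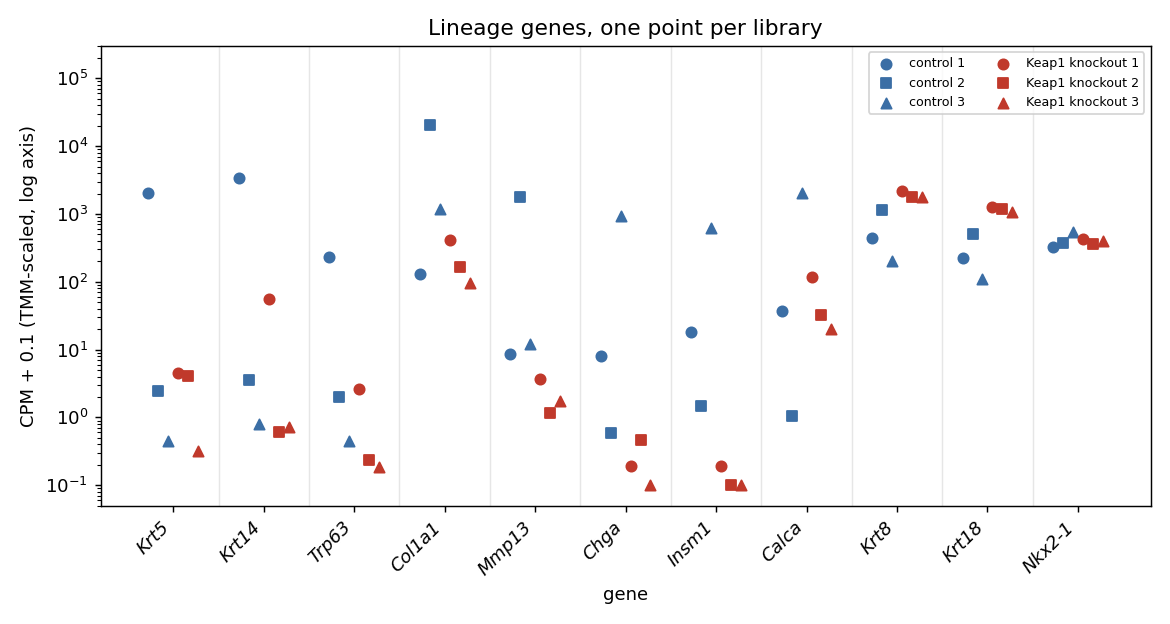
Levels of lineage genes as CPM plus 0.1 on a log axis, 1 point per library (blue control, red Keap1 knockout, marker shape by sample number). Krt5, Krt14 and Trp63 peak in control 1, Col1a1 and Mmp13 in control 2, and Chga, Insm1 and Calca in control 3.

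Against this background, tumours with Keap1 knockout carried far more RNA of detoxifying enzymes and of a few genes hardly seen in controls. Eomes, a T-box transcription factor (ENSMUSG00000032446), stood at 0.517 ± 0.331 CPM in controls and 977 ± 74.9 CPM in knockouts (SD, n = 3 each), a log2 fold change of 10.87 ± 0.69 (SE). Sdr16c6, a dehydrogenase family gene without a read in any control, was at least 2763-fold higher, against a floor of 3 counts over the group. Among genes that fell were the adhesion gene Cdh2 (N-cadherin), from 97.0 ± 80.1 to 0.515 ± 0.0520 CPM, the axon guidance receptor gene Robo1, from 143 ± 147 to 1.48 ± 0.332 CPM, and the neural RNA-binding protein gene Msi1, from 58.4 ± 48.2 to 0.425 ± 0.122 CPM. In all, 771 genes changed by edgeR's quasi-likelihood test at an adjusted p below 0.05, 433 higher and 338 lower in the knockout, and in each of the 771 all 3 libraries of one group lay beyond those of the other. Of all tested genes, 40.7% were separated in this way, against 10% expected by chance. Genes vary together, so the share in a single grouping can lie far from 10%, and its spread was not computed. The edgeR count was 735 without control 1 (426 shared), 269 without control 2 (190 shared, Cdh2 not among them at an adjusted p of 0.0718), 3209 without control 3, and 2 (Slc30a3 and Calr3), 0 and 0 without knockouts 1, 2 and 3, where 3758, 3372 and 3321 genes had an unadjusted p below 0.05 and limma voom called 42, 0 and 0. DESeq2 called 4122 genes and edgeR without the filter 465, and with the level of Xist as a term, added after the data were seen because this transcript of female cells was high in control 2 and knockouts 2 and 3, edgeR called 24.

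The other genes with the largest rises, by the rule fixed in advance, were Ces1g, BC051665, Pga5, Trim54, Ms4a15, Tdo2, Gsta2 and Spink1. Ces1g, a carboxylesterase gene with 3 reads in the controls, was 15381-fold higher by the ratio of reads pooled over each group to their pooled totals, with a 95% counting interval of 5263 to 74586. BC051665 and the pepsinogen gene Pga5 had no reads in controls and were at least 643-fold and at least 501-fold higher. Tdo2, which encodes the tryptophan-degrading enzyme of the kynurenine route, rose from 0.400 ± 0.228 to 124 ± 89.2 CPM, and the trypsin inhibitor gene Spink1 from 0.0991 ± 0.172 to 22.3 ± 11.6 CPM (SD, n = 3 each). The other genes with the largest falls were Trank1, Bcat1, Shank1, Hoxb8, Sox21, Akap6 and Nav3. Bcat1, which encodes the cytosolic branched-chain aminotransferase, was 417-fold lower (95% counting interval 143 to 2022), with 18.9 ± 14.6 CPM in controls. Shank1, a scaffold gene of synapses, fell by 7.43 on the log2 scale (SE 1.21), and the neural progenitor factor Sox21 by 6.12 (SE 1.03). Ces1g and Gsta2 have near-identical relatives with which reads can be shared, so their levels are less certain. In the edgeR test the calls of Tdo2, Spink1, Trank1, Bcat1, Shank1, Hoxb8 and Nav3 ended without control 1 (adjusted p from 0.0526 to 0.0576), those of Pga5, Ms4a15, Tdo2, Gsta2, Bcat1, Hoxb8, Sox21, Akap6 and Nav3 without control 2 (0.0520 to 0.0852), and all of them without knockout 1, 2 or 3 (0.0639 to 0.228).

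Many NRF2 target genes rose. Of 74 tested members of 5 lists fixed in advance, 35 rose and none fell, in 61 every knockout library lay above every control library, and in 3 (Slc40a1, Fech and Abcg2, chosen after their values were seen) every knockout library lay below. In glutathione and thioredoxin metabolism, 8 of 15 members rose (12 when adjusted over the list alone), with a median log2 fold change of 3.62. Both subunits of the enzyme that limits glutathione synthesis were among them: Gclc rose from 198 ± 120 to 4764 ± 1229 CPM and Gclm from 85.3 ± 27.8 to 1183 ± 223 CPM (SD, n = 3 each). Txnrd1, the cytosolic thioredoxin reductase gene, rose from 222 ± 39.4 to 2739 ± 524 CPM, and Srxn1 (sulfiredoxin) by a log2 fold change of 3.86 ± 0.28 (SE), with an adjusted p of 0.0108 by edgeR's quasi-likelihood test. The cystine transporter gene Slc7a11 had a log2 fold change of 4.66 ± 1.61 (SE) and did not pass, with an adjusted p of 0.122 by the same edgeR test, but did in 4 of 15 alternatives, namely limma voom, with 1 spread or a spread per genotype, edgeR without control 1 and DESeq2 (adjusted p of 0.00272). Its controls ranged from 2.49 to 178 CPM.

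In xenobiotic and carbonyl detoxification, 17 of 34 members rose (27 when adjusted over the list alone), with a median of 3.31. Nqo1, a quinone reductase gene widely used as a readout of NRF2, stood at 49.6, 15.0 and 3.58 CPM in controls 1 to 3 and rose to 1089 ± 230 CPM in knockouts (SD, n = 3), with an adjusted p of 0.0454 by edgeR's quasi-likelihood test, and Gstm1 from 84.4 ± 51.2 to 6885 ± 185 CPM, which made it the gene with the most reads in each knockout library. Aox1 and Cbr1 rose by log2 fold changes of 3.30 ± 0.19 and 3.67 ± 0.29 (SE). Glutathione transferase, carbonyl reductase and Cyp2a genes come in families of near copies, so how the authors' counting shared reads among them is uncertain. In NADPH supply, 4 of 8 members rose (7 over the list alone, median 2.15): Taldo1, Idh1, Pgd and Pgls. G6pdx, the entry enzyme of the pentose phosphate pathway, had a log2 fold change of 2.99 ± 0.85 (SE) and did not pass, at an adjusted p of 0.0859 by the edgeR test, but did in 3 of 15 alternatives, namely limma voom with a spread per genotype, edgeR without control 1 and DESeq2 (0.00338). In heme and iron handling, 3 of 9 members rose (Blvrb, Slc48a1 and Ftl1, median 1.04), and when adjusted over the list alone 3 were higher and 1, the iron exporter gene Slc40a1, was lower, while Hmox1, the inducible heme oxygenase gene, stood at 60.6 ± 33.1 and 121 ± 41.2 CPM without passing. Of 8 efflux transporters, Abcc1, Abcc2 and Abcc5 rose (median 2.59), and when adjusted over the list alone 5 were higher and 1, Abcg2, was lower.

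By camera with its preset correlation of 0.01, these 5 lists ranked above other genes, with adjusted p of 7.06e-10 for glutathione and thioredoxin, 1.78e-17 for detoxification, 8.58e-06 for NADPH supply, 0.0333 for heme and iron and 0.0364 for efflux. With an estimated correlation camera gave an adjusted p of 0.580 for the first 4 and 0.777 for efflux, so none of the calls held after adjustment. The unadjusted p by that test were 0.0349, 0.0246, 0.0592, 0.0748 and 0.152 in the same order, in a fit with 4 residual degrees of freedom. The test fry, which asks whether a list moves one way without comparing it with other genes, passed the first 4, with adjusted p of 0.00973, 0.00973, 0.0134 and 0.0123, and gave 0.0518 for efflux. Without any one library, the list medians lay between 3.16 and 4.09 for glutathione and thioredoxin, 3.09 and 3.65 for detoxification, 1.92 and 2.57 for NADPH supply, 2.22 and 2.99 for efflux, and 0.62 (without control 3) and 1.45 for heme and iron. Without control 2 the edgeR test called 6, 7, 2, 1 and 1 members of the 5 lists in this order, with Nqo1 at an adjusted p of 0.0822 and Gclc at 0.0625, and without knockout 1, 2 or 3 it called none, where Srxn1 had adjusted p of 0.0639, 0.125 and 0.102.

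**Figure D3:**
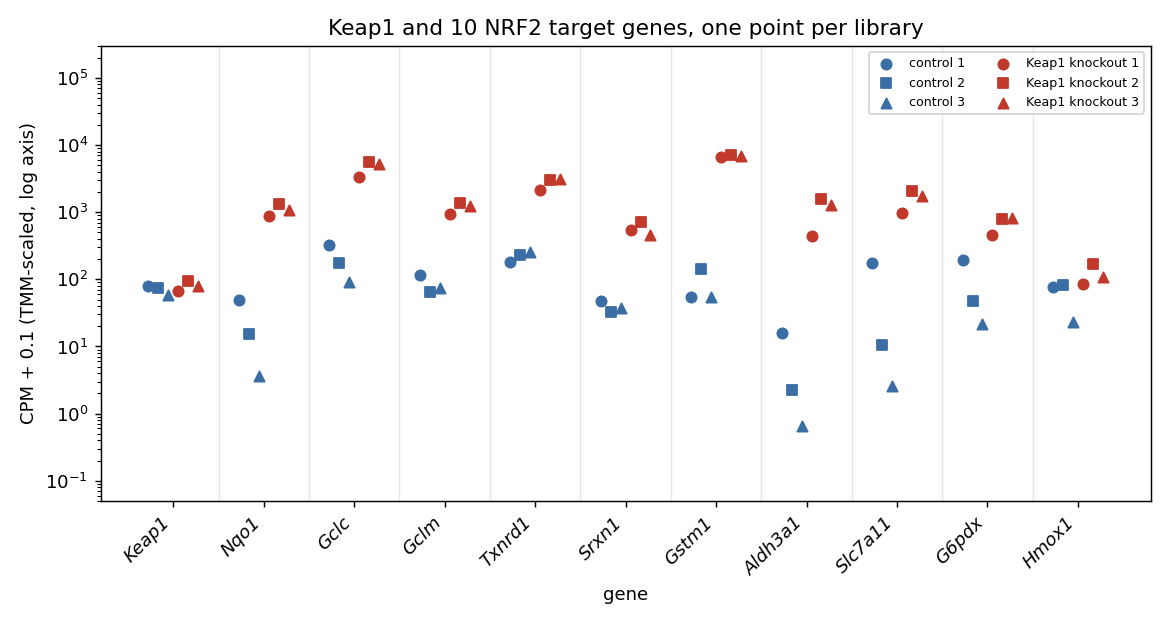
Levels of Keap1 and 10 NRF2 target genes as CPM plus 0.1 on a log axis, 1 point per library (blue control, red Keap1 knockout, marker shape by sample number). For each of the 10 targets the 3 knockout libraries lie above the 3 controls, with the narrowest separation at Hmox1, while Keap1 overlaps between the groups. Aldh3a1 was chosen after its values were seen.

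Of 14 components of the pathway itself, Maff, a small MAF partner of NRF2, was the 1 that passed, rising from 23.7 ± 4.24 to 57.4 ± 8.87 CPM (SD, n = 3 each). Nfe2l2, which encodes NRF2, stood at 138 ± 74.8 CPM in controls and 160 ± 5.93 CPM in knockouts, with a log2 fold change of 0.21 ± 0.46 (SE) and an adjusted p of 0.779 by edgeR's quasi-likelihood test. The camera test of this list gave an adjusted p of 0.236. Of 21 genes of the ATF4 response and serine synthesis, Asns (asparagine synthetase) and Slc3a2, the partner chain of the cystine transporter, rose by log2 fold changes of 1.53 ± 0.27 and 2.14 ± 0.37 (SE). The list ranked higher by camera with an adjusted p of 0.0364, which became an adjusted p of 0.857 with an estimated correlation, 0.197 without control 3 and 0.0722 without knockout 2. Camera also gave 0.0530 under the filter of 1 CPM in 3 samples and 0.0503 with Xist level as a term. With fry (0.279), the call was lost in 6 of 15 alternatives. The oncogene Myc rose from 28.3 ± 7.88 to 105 ± 7.19 CPM, a log2 fold change of 1.90 ± 0.25 (SE) and an adjusted p of 0.0308 by the edgeR test, whereas Mycl had a log2 fold change of 0.22 and Mycn one of -2.91 without passing (both chosen after their values were seen). The edgeR calls of Maff, Asns, Slc3a2 and Myc ended without control 2 (adjusted p from 0.0608 to 0.0769) and without knockout 1, 2 or 3 (0.124 to 0.232), and those of Maff and Asns also without control 1 (0.0598 and 0.0596).

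Most neuroendocrine and neuronal genes had negative log2 fold changes, 15 of 16 and 19 of 20 tested, but none passed singly in the edgeR test, with 8 and 14 at an unadjusted p below 0.05. On these lists limma voom called 0 and 0 and DESeq2 called 1 and 8. Insm1, with 2 reads over the 3 knockouts, was at 18.0, 1.39 and 622 CPM in controls 1 to 3, with an adjusted p of 0.0712 by edgeR's quasi-likelihood test. The 16 tested neuroendocrine genes had a median log2 fold change of -4.47 and a camera adjusted p of 0.0910, and without control 3 the median was -0.62. Another 7 members, Chgb, Dll3, Scg2, Scg3, Scg5, Resp18 and Pcsk1n, had nearly all their reads in control 3 and were removed by the filter. Without control 2 or knockout 1, 2 or 3 the filter let these 7 in, and camera on the 23 members gave an adjusted p of 0.00138, 0.0338, 0.0309 and 0.0418, which was not a test of the same 16 genes. The list also passed camera without the filter (adjusted p of 0.0110), and on the same 16 genes with the sample number as a block (0.00710) and in the voom fit with a spread per genotype (0.0186), 7 of 15 alternatives in all, but not with an estimated correlation (0.857) or by fry (0.660). The 20 tested neuronal and synaptic genes, such as Stmn3 and Elavl3, had a median of -4.37, and 13 were lower when adjusted over the list alone. That list ranked lower by camera with an adjusted p of 0.00648, an adjusted p of 0.857 with an estimated correlation and one of 0.510 by fry. Its median was -1.70 without control 3. Yap1, high in tumours that lack neuroendocrine features, had a log2 fold change of 0.55 ± 0.67 (SE), which ran from 0.066 to 0.995 over the alternatives. It stood at 88.6, 81.8 and 12.3 CPM in controls 1 to 3 and at 89.1 ± 5.77 CPM in knockouts (SD, n = 3). Of 27 genes on the list of non-neuroendocrine and YAP-associated genes edgeR called 0, with 1 at an unadjusted p below 0.05, limma voom 0 and DESeq2 1. The camera adjusted p of that list was 0.236, with a median of 0.04, and an adjusted p of 0.857 with an estimated correlation. Camera placed it higher without control 1 and without control 2, at adjusted p of 0.0264 and 0.0315 and medians of 0.75 and 0.44, whereas without control 3 the direction turned, with a median of -0.40 and an adjusted p of 0.318.

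Of the Notch pathway, 3 of 19 members fell and none rose: Lfng, which modifies Notch receptors, by 2.30 on the log2 scale (SE 0.31), the Notch effector Rbpj by 1.03 (SE 0.16) and the coactivator gene Maml3 by 1.69 (SE 0.33). When adjusted over the list alone, 6 members were lower and 1 was higher. The list had a median of -1.03 and a camera adjusted p of 0.0364, which was an adjusted p of 0.580 with an estimated correlation. It was 0.0507 by camera under the filter of 1 CPM in 3 samples, and fry gave an adjusted p of 0.124. Sox2, a factor of basal and neural progenitors, fell from 124 ± 72.7 to 4.61 ± 1.22 CPM, and Avil, on the tuft cell list, from 21.9 ± 10.3 to 1.51 ± 0.328 CPM (SD, n = 3 each). Among genes often deleted in mouse models of this cancer, Rbl2 fell by 1.76 on the log2 scale (SE 0.35, adjusted p of 0.0494 by the edgeR test). Rb1 stood at 162 ± 87.9 and 63.9 ± 9.66 CPM and Trp53 at 17.0 ± 3.27 and 27.8 ± 3.74 CPM in controls and knockouts, without passing. The edgeR calls of Lfng, Rbpj, Maml3 and Avil ended without control 2 (adjusted p from 0.0582 to 0.0660), those of Maml3 and Rbl2 without control 1 (0.0670 and 0.0706), and all of these and that of Sox2 without knockout 1, 2 or 3 (0.138 to 0.236).

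Few or no single genes of the proliferation, proteasome and MHC class I lists passed. Of 30 proliferation genes only Ube2c, of the mitotic ubiquitin ligase pathway, rose, from 139 ± 14.7 to 315 ± 69.7 CPM (SD, n = 3 each), and the median of the list was 0.39, while Mki67 had a log2 fold change of -0.57 and Top2a one of -0.04 (both chosen after their values were seen). The camera adjusted p was 0.00682, an adjusted p of 0.857 with an estimated correlation and one of 0.124 by fry, and the list median was 0.26 without control 1. The call of Ube2c ended without control 1 or 2 (adjusted p of 0.0706 and 0.0711 by edgeR) and without knockout 1, 2 or 3 (0.138, 0.233 and 0.226). Of 32 proteasome genes edgeR called 0, with 10 at an unadjusted p below 0.05, limma voom 0 and DESeq2 2. Their median was 0.31, and 27 were positive, with a camera adjusted p of 0.00109, an adjusted p of 0.580 with an estimated correlation and one of 0.0446 by fry. All 15 MHC class I presentation genes had positive log2 fold changes, with a median of 0.60 and 0 past the edgeR test singly (2 at an unadjusted p below 0.05, 0 by limma voom, 2 by DESeq2), a camera adjusted p of 0.00526, an adjusted p of 0.857 with an estimated correlation and one of 0.388 by fry. That median was 0.27 without control 3 and 1.02 without control 1. The median over all tested genes was -0.08 under the scaling used and -0.18 without scaling, and these 3 list medians were also positive under RLE and upper-quartile scaling.

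Of the marker lists of other cell types, 2 passed camera with preset correlation and none with an estimated one. Macrophage and monocyte markers had a median log2 fold change of -1.19 over 22 genes, of which edgeR called 0 over all genes (9 at an unadjusted p below 0.05, 0 by limma voom, 7 by DESeq2) and 5 when adjusted over the list alone, among them Mertk, C1qc, C1qb and Fcgr1. The median was -0.57 without control 2. Camera gave an adjusted p of 0.00648, an adjusted p of 0.857 with an estimated correlation, and fry one of 0.493. Fibroblast and matrix markers had a median of -2.37, and 1 of 25, the matrix gene Fbln1, fell, from 199 ± 139 to 7.27 ± 4.15 CPM (SD, n = 3 each). The camera adjusted p was 0.0364, an adjusted p of 0.857 with an estimated correlation and one of 0.476 by fry. By camera it was 0.139 without control 2, the library richest in Col1a1, 0.210 without control 3 and 0.0948 without knockout 3. In the other direction, camera gave 3.14e-05 without control 1, and the call held without knockouts 1 and 2 (0.0473 and 0.0300). The median was -1.50 without control 2 and -1.49 without control 3. The call of Fbln1 ended without control 2 (adjusted p of 0.0539 by edgeR) and without knockout 1, 2 or 3 (0.138, 0.220 and 0.198). Club and secretory cell markers had a median of 0.01, which was -0.02 under RLE scaling and ranged from -0.37 without control 3 to 0.86 without control 1. There, 3 of 18 rose, namely Scgb3a2, Aldh1a7 and Cyp2a5, of which Aldh1a7 and Cyp2a5 were also on the NRF2 detoxification list. Their edgeR calls ended without knockout 1, 2 or 3 (adjusted p from 0.0719 to 0.217), that of Scgb3a2 without control 1 (0.0618) and those of Aldh1a7 and Cyp2a5 without control 2 (0.0587 and 0.0608). Alveolar, ciliated, endothelial, smooth muscle, T and NK cell, B cell, neutrophil and red cell markers gave camera adjusted p of 0.281, 0.683, 0.450, 0.450, 0.572, 0.236, 0.683 and 0.646. Camera placed alveolar markers higher without control 2 (adjusted p of 0.0435), without the filter (0.0204) and with the sample number as a block (0.0444). Their median lay between -0.05 and 1.29 without any one library. Endothelial markers were lower by camera without control 3 (0.0296), and B cell markers higher without the filter (0.0204). Eomes was the one T and NK cell marker that rose, while the list median was -0.52 (0.27 without control 2), camera placed the list lower and fry higher, both without passing.

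**Figure D4:**
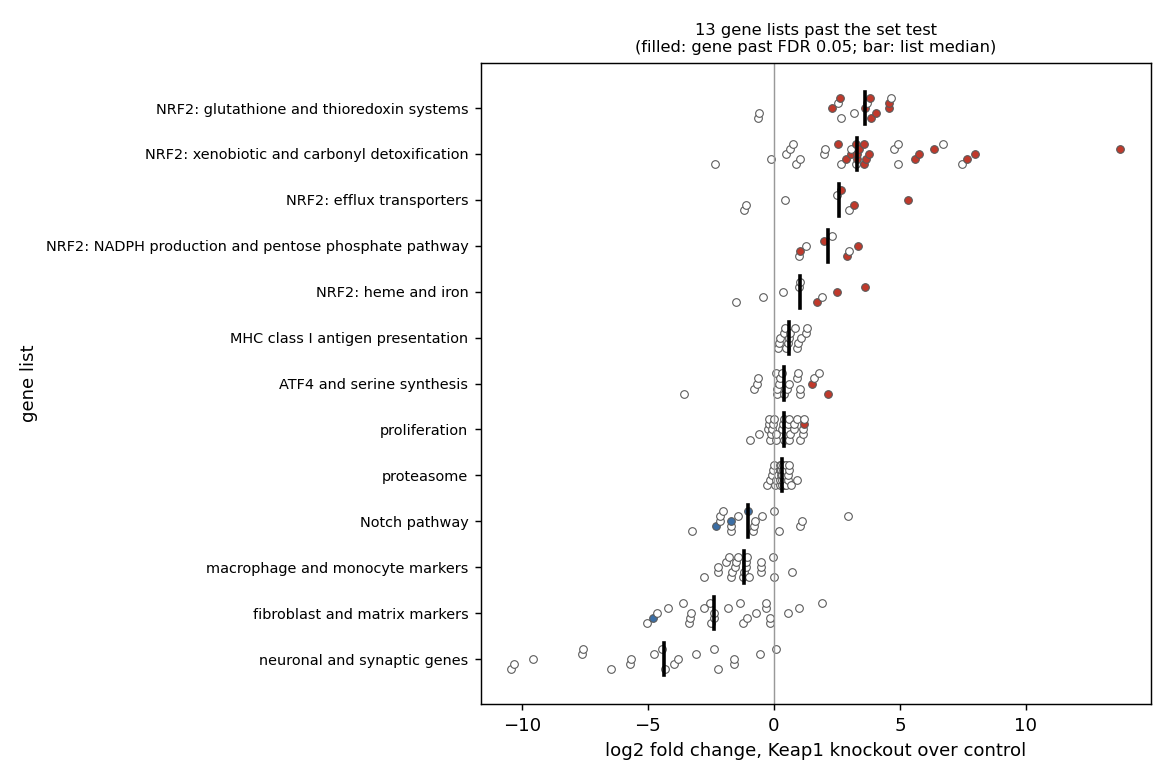
Log2 fold change of each tested member of the 13 gene lists past the camera test with preset correlation, Keap1 knockout over control, 1 point per gene. Filled points passed the edgeR test over all genes (red higher, blue lower), and the bar marks the median of each list, from 3.62 for glutathione and thioredoxin to -4.37 for neuronal and synaptic genes.

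Over the 41 lists, camera placed 9 higher and 4 lower, fry passed 5, and camera with an estimated correlation passed none. In the authors' deposited table of a DESeq2 comparison, which lists genes by symbol, 3998 had an adjusted p below 0.05, 1594 higher and 2404 lower in the knockout. Among 16781 genes matched by symbol to those tested here, 99.7% had the same sign of fold change. All 748 matched genes that changed in the edgeR test were past an adjusted p of 0.05 in the authors' deposited table with the same sign. Both comparisons used the same samples, and DESeq2 as run here also called all 771 edgeR genes, so this overlap is not independent support. In the authors' deposited table Nqo1 had a log2 fold change of 5.57 and Eomes one of 10.87. Genes past the threshold there but not in the edgeR test included Slc7a11, G6pdx, Rb1, Mycn, Stmn3 and Mertk, with adjusted p of 0.00285, 0.00354, 0.0391, 0.0149, 0.000786 and 0.00390 by DESeq2.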

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

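The limma voom fit with a spread per genotype, the fit with Xist level as a term and the added thresholds per direction were chosen after the data were seen. The 771 changed genes (433 higher, 338 lower) stayed within 1.5 times under RLE scaling (787, of which 756 shared), upper-quartile scaling (797, all 771 shared), a filter of 1 CPM in 3 samples (943, of which 725 shared), the log2 fold threshold of 1 (722) and voom with a spread per genotype (853, of which 570 shared). The count was 465 (283 higher, 182 lower) without the filter, 4122 (1651 and 2471) by DESeq2, 24 (19 and 5) with Xist level as a term, and 3117 (1475 and 1642) at an adjusted p below 0.10. Limma voom called 1067, of which 664 were higher. Leaving out 1 library gave 0 to 3209 genes, 0 to 1568 higher and 0 to 1641 lower. The lowest counts came without knockout 2 or 3, where edgeR's smallest adjusted p was 0.125 and 0.102, 3372 and 3321 genes had an unadjusted p below 0.05 and voom called 0 and 0, and the highest came without control 3. A fit without 1 library has 3 residual degrees of freedom in place of 4, whichever library is left out. This alone therefore does not account for the lower counts without a knockout than without a control. The common coefficient of biological variation, edgeR's measure of spread between samples, was 0.692 among controls alone and 0.272 among knockouts alone. Whether this difference in spread set the counts was not tested. Deviations of same-numbered samples of the 2 groups correlated at 0.0176, 0.00012 and 0.0507. These values gave no sign of pairing by sample number, but with so few samples per group they cannot exclude it. With the number as a replicate block edgeR called 0 genes (0 higher and 0 lower), 4026 had an unadjusted p below 0.05, voom with the same block called 13, and 17 lists passed camera. The lists past camera numbered 13, from 14 to 16 over the left-out libraries, 20 without the filter, 5 by fry and 0 with an estimated correlation, and the cause was not tested. Keap1 had log2 fold changes of 0.07 to 0.32 and did not pass in any of these settings. Over the named genes and all alternatives, 1234 results kept their side of the threshold, 364 lost a call and 70 gained one, and over the lists 553, 30 and 32, and none reversed. The authors' deposited table had 3379 genes past an adjusted p of 0.05 with a log2 fold change of at least 1 in size. At the depth and spread of these libraries 5 of 67 simulated log2 changes of 2 were recovered, and other depths were not simulated.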

Other observations

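Some further genes separated the groups and were chosen after their values were seen. Adh7, which encodes a retinol and alcohol dehydrogenase, rose from 11.8 ± 14.2 CPM in controls to 2343 ± 877 CPM in knockouts (SD, n = 3 each), the calcium channel gene Trpv6 from 1.92 ± 0.832 to 163 ± 40.0 CPM, and the iodide transporter gene Slc5a5 from 1.81 ± 1.09 to 134 ± 40.7 CPM. The endoderm factor gene Gata6 rose from 23.2 ± 9.19 to 97.2 ± 3.68 CPM. The edgeR calls of these 4 ended without knockout 1, 2 or 3 (adjusted p from 0.0639 to 0.220), and those of Adh7 and Gata6 also without control 2 (0.0614 and 0.0591). The maternally expressed transcript Meg3 fell from 61.0 ± 67.1 to 2.63 ± 0.266 CPM, a call that ended without control 2 (adjusted p of 0.0638 by edgeR) and without knockout 1, 2 or 3 (0.187, 0.236 and 0.233), while H19, also imprinted, stood at 9.18 ± 12.2 and 238 ± 80.7 CPM with an adjusted p of 0.0806 by edgeR's quasi-likelihood test. The keratins of simple epithelia Krt8 and Krt18 stood at 592 ± 484 and 281 ± 208 CPM in controls and at 1922 ± 244 and 1162 ± 101 CPM in knockouts, without passing. In the authors' deposited DESeq2 table H19 and Krt18 had adjusted p of 0.000313 and 0.00978, and Krt8 one of 0.0605. Albumin reads numbered 636 in knockout 1 and 109 in knockout 3 and at most 2 elsewhere.

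The tests in this part were chosen after the result was seen, except the thinning of depth. Bounds for the neuroendocrine and NRF2 patterns were set with the member values already known. The first pattern is that knockout libraries were more alike than controls, with mean correlations of 0.970 and 0.849. Lower depth of the controls is argued against: with all libraries thinned to the same total, the gap in mean correlation was 0.120 against 0.121 before. A single animal as the source of all 3 knockout libraries is excluded, since 1 of the 3, knockout 1, had over 10 CPM on 4 Y-linked genes (147 CPM, against 0.916 and 0.0879 CPM in knockouts 2 and 3), although knockouts 2 and 3 may still share an animal. Different tissue or tumour types among the controls, and an effect of Keap1 loss itself, stay open.

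The second pattern is the low neuroendocrine level in knockouts, a median difference of -2.81 in log2(CPM + 1) over the 23 list members. Against control 2 alone the median was -0.0744, while 10 of 23 members were above every knockout library in control 2, 16 in control 1 and 22 in control 3, where chance gives 5.75, so whether the knockouts lie below every control stays open. The median was -1.30 against control 1 alone and -6.63 against control 3 alone. Without control 3 it was -0.902 (0.217 as MAD over the square root of n), too near the bound of -1 to say whether control 3 alone sets the difference. Here and below, that measure treats genes as independent and does not measure the spread between libraries. The 16 tested members had an estimated correlation of 0.711. Whether Keap1 loss lowers the program or these tumours differ in kind cannot be told apart with 1 strongly neuroendocrine control.

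The third pattern is the rise of NRF2 targets, a median log2 fold change of 2.95 over 74 genes. More airway secretory cells in the knockouts is argued against, since the 16 club cell markers on no NRF2 list had a median of -0.0293 (MAD over the square root of n 0.340), between -0.50 and 0.58 without any one library against 2.62 to 3.32 for the targets, although Scgb3a2 rose and Scgb1a1 stood at 831 ± 638 and 3468 ± 1879 CPM. Reads shared within gene families do not account for it, since the 26 targets outside those families had a median of 2.74 (0.356 by the same measure), with 13 past the test. Loss of KEAP1 control over NRF2 is the explanation the design offers, and it may hold, but it was not separable here from other differences between the 2 groups of tumours.

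The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 771 genes and the highest of the other splits 0, so 1 of 10 gave as many. Every other split mixed the genotypes, which adds the genotype difference to the spread within its groups. Of all tested genes, 40.7% were separated by genotype. The 0 is therefore not the count to be had without a genotype difference, and 771 against 0 cannot be read as such a comparison. For gene lists past camera, the real split gave 13 and the highest other 23, and 9 of the 10 gave as many. The camera p for the detoxification list was 4.33e-19 in the real split and 3.36e-09 at its smallest in the others.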
